A study of Arabidopsis thaliana with 8 samples.

How the data were processed

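RNA was extracted from the terminal 1 cm of roots of seedlings grown vertically on 1/2 MS medium for 7 days at 22 °C with 16 h of light and 8 h of dark, and TruSeq RNA libraries were sequenced on a HiSeq2000 with 6 barcoded libraries per pool, per the labels' protocols. The 8 libraries were grouped by their titles into 4 groups of 2, and the labels do not say which libraries shared a pool. Reads were processed with TopHat and Cufflinks and the TAIR10 build, per the submitters' processing notes, and versions and settings are not given in the sources used here. 3 tables were used, each with 1 value per group, a fold change, a p-value and a q-value for 33557 genes. The group values deposited by the authors were read as FPKM, fragments scaled by transcript length and library size, because Cufflinks is named in the notes; the headers name only the groups. Their sums run from 960451 to 1148755 per group and differ between groups, unlike those of TPM or CPM. The fold change is the ratio of the 2 group values as the authors deposited it. The p-value and q-value are those deposited by the authors, whose test is not named in the sources used here. The smallest p is 5e-05, shared by 2612, 5421 and 2265 genes of the ABA, bin2-1 and bzr1-D comparisons, so the smallest q were 0.000385, 0.000188 and 0.000451 and do not rank the genes that share them.

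A group found in 2 tables had values that differed by a near-constant factor: untreated wild type by 0.938 between the ABA and bin2-1 tables (range 0.936 to 0.944 over 18195 genes), and bin2-1 by 1.04 between the bzr1-D and bin2-1 tables (1.02 to 1.05). Levels were therefore compared within a table, and a log2 fold change of bzr1-D/bin2-1 against wild type is the sum of 2 log2 fold changes from separately scaled tables. The depth of the libraries is unknown, and the precision of the group values cannot be read from the tables. A count model, a fit per library and replicate errors need values per library, which were not analysed here.

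The log2 fold change is the log2 of the deposited ratio, with no pseudocount, and none is given where a group is listed at 0. A gene past the threshold with 1 group listed at 0 was counted as changed at least 2-fold and at least 4-fold. A gene was counted as tested where its p is below 1, and a Benjamini-Hochberg adjustment recomputed over those genes gave the same counts past the threshold in each table. Genes at q under 0.05 count as past the threshold. The median log2 fold change of genes with at least 1 FPKM in both groups was 0.008, -0.021 and -0.009 in the 3 comparisons. Gene names come from the RefSeq annotation of TAIR10.1, which holds 32810 of the 33557 identifiers. It was otherwise used for gene order, annotated products, gene lengths and types, and the span of windows, from which the least gene-dense windows were taken. No coordinates are printed. The strand setting of the counting is not given in the sources used here, so reads of an overlapping or antisense partner may be counted with a gene, and near-identical copies such as KIN1 and KIN2, CYP71A12 and CYP71A13 or the LHCB1 genes may share reads.

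Before the data were examined, 20 gene lists of 254 genes, the comparisons, the alternatives and the rule for named genes were fixed. For each list the members past the threshold were counted over all genes and adjusted over the list alone, and the list median was placed among the medians of 10000 random lists matched on mean expression in 20 bins; genes of a list are not independent, so the percentile describes these libraries. The named genes are ABI5, BIN2 and BZR1, the 6 largest rises and 6 largest falls past the threshold with at least 5 FPKM in the higher group and a value above 0 in the lower, the 2 members of each list with the largest finite change past the threshold, and 4 genes per direction pattern of each overlap. List members outside this rule, such as COR15A, MYB102, HAI2, HAI3 and CPD, were named after their values were seen. Overlaps were counted among genes tested in both tables and set beside the overlap of independent lists, which is not matched on expression. The shared group was simulated 100 times with no effect, with noise taken from the deposited p and fold changes. Genes changed at least 4-fold were counted in windows of 100 tested genes in chromosome order and set against 1000 shuffles within the genome; this count, 6 further gene lists and 3 families taken by gene symbol were chosen after seeing the data. On data simulated from the 20126, 20404 and 20410 tested genes of the ABA, bin2-1 and bzr1-D tables, with 200 genes changed, the adjustment recovered 84%, 83% and 83% of 2-fold and 97%, 93% and 96% of 4-fold changes, and 4.23%, 2.76% and 5.79% of its calls were false. The simulated p used the same error as the simulated noise, so these shares do not measure the authors' test. Alternatives were a q under 0.01, a minimum of 2-fold, a filter at 1 FPKM, a recomputed adjustment, centring on the median and pseudocounts of 1 and 0.1 FPKM. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.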

Results

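RNA was sequenced from the terminal 1 cm of roots of 7-day-old Arabidopsis thaliana seedlings of the Columbia background. The 8 libraries form 4 groups of 2: wild type without ABA, wild type treated with 100 µM ABA for 3 h, bin2-1, and bzr1-D/bin2-1. ABA (abscisic acid) is a stress hormone. BIN2 is a GSK3-like kinase that represses brassinosteroid signalling, and the bin2-1 allele makes a hyperactive kinase. BZR1 is a transcription factor downstream of BIN2, and bzr1-D makes a stabilised form of it. The second library of each group is labelled a repeat, and the labels do not say whether its roots came from separately grown plants. The p-values can therefore speak for these libraries only. The authors' test is not named, so how far the p-values reflect the spread between the libraries is unknown. The labels do not state whether the mutant roots received ABA. The 3 tables each hold 1 FPKM value per group for 33557 genes, and no values per library were used here, so no replicate error stands beside a group value. The depth of the libraries is unknown. All p and q are those of the authors.

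The title of the series asks about brassinosteroid and ABA signalling in the root through BZR1 and ABI5 (AT2G36270, on chromosome 2), a transcription factor of ABA responses. With ABA, ABI5 rose 9.55-fold in the authors' deposited table, from 0.937 to 8.94 FPKM (q = 0.000385). In bin2-1 against wild type it rose 3.22-fold in the authors' deposited table, from 0.998 to 3.22 FPKM (q = 0.000188). In bzr1-D/bin2-1 against bin2-1 it fell 2.70-fold in the authors' deposited table, from 3.35 to 1.24 FPKM (q = 0.000451). BIN2 (AT4G18710, chromosome 4) had 96.0 FPKM without ABA and 93.6 with ABA (q = 0.913 in the authors' deposited table). BIN2 fell in bin2-1 from 102 to 66.1 FPKM (log2 fold change -0.63, q = 0.000188 in the authors' deposited table), and in bzr1-D/bin2-1 against bin2-1 it had 72.9 and 68.9 FPKM (q = 0.734). BZR1 (AT1G75080, chromosome 1) had 67.7 FPKM without ABA and 66.8 with ABA (q = 0.953 in the authors' deposited table). BZR1 fell from 72.2 to 34.4 FPKM in bin2-1 (log2 fold change -1.07, q = 0.000188 in the authors' deposited table) and from 35.8 to 27.1 FPKM in bzr1-D/bin2-1 against bin2-1 (log2 fold change -0.40, q = 0.0247). The bin2-1 and bzr1-D alleles change the protein, so these transcript levels do not check the genotype labels. Values of 1 group differ between tables by a near-constant factor.

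**Figure D1:**
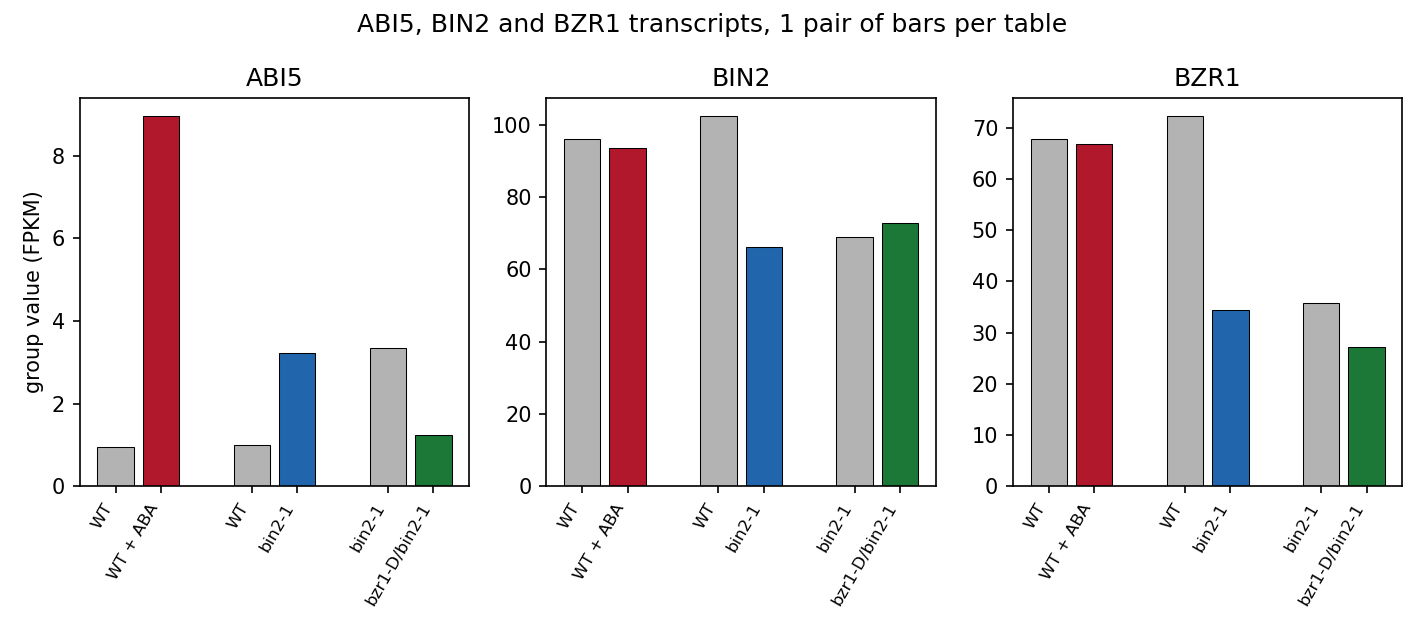
Group values (FPKM, vertical axis from 0) of ABI5, BIN2 and BZR1, with 1 pair of bars for each of the 3 tables: grey for the reference group and colour for the group compared with it. WT stands for wild type, and no error bars are drawn because the tables hold 1 value per group. ABI5 is highest with ABA, at 8.94 FPKM, and BZR1 is lowest in bzr1-D/bin2-1, at 27.1 FPKM.

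ABA raised 3046 of 20126 tested genes in wild-type roots and lowered 1913, at q under 0.05. The comparison asks which genes the hormone changes in roots. Among genes past the threshold that reached 5 FPKM with a value above 0 in both groups, the largest rises were of genes of the ABA and drought response: in the authors' deposited table the log2 fold change was 10.40 for RD29B, 10.17 for LEA4-5, a late embryogenesis abundant protein, 9.47 for TSPO, an ABA-induced membrane protein, and 9.20 for the dehydrin RAB18. RD29B went from 0.278 to 377 FPKM and LEA4-5 from 0.654 to 754 FPKM. AT3G17520 and AT1G49450 rose by log2 fold changes of 9.11 and 8.99 in the authors' deposited table. The largest fall was of the ABA receptor PYL6, 70.3-fold in the authors' deposited table. It was followed by AT1G44050, AT5G48430, AT2G36690 and AT4G28811, with log2 fold changes from -5.57 to -4.53 in the authors' deposited table. NIP2;1, an aquaporin-like channel that is also induced in low oxygen, fell from 1642 to 84.4 FPKM (-4.28 on the log2 scale in the authors' deposited table). These q lie at 0.000385, the smallest in the authors' deposited table, except RAB18 at 0.00534. Of the 4959 genes past the threshold, 2236 changed at least 2-fold.

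The ABA pathway itself changed at several steps. Among the ABA-responsive genes, 17 of 20 tested members rose and 1 fell, with a median log2 fold change of 5.98. The member that fell was ADH1, alcohol dehydrogenase, which is also a low-oxygen gene (-1.11 in the authors' deposited table), and COR15A and MYB102 had 10.41 and 6.47 in the authors' deposited table without passing (q = 0.475 and 0.194). Of the clade A PP2C phosphatases, which hold the pathway off, 7 of 9 tested members rose and 0 fell: HAI1 went from 0.853 to 311 FPKM and ABI2 from 2.07 to 86.4 FPKM (log2 fold changes 8.51 and 5.39 in the authors' deposited table), while HAI2 and HAI3 stood at 9.45 and 9.17 without passing (q = 0.194 for each). Among the ABA receptors 2 of 10 tested members rose and 7 fell, among them PYL5 at -3.35 in the authors' deposited table. In the list of ABA transcription factors and SnRK2 kinases 6 of 8 tested members rose and 0 fell, with ABF3 at 3.58 beside ABI5 at 3.26 in the authors' deposited table. For ABA synthesis and breakdown, 7 of 9 tested members rose and 0 fell: NCED3, which makes an ABA precursor, and CYP707A1, which breaks ABA down, had log2 fold changes of 6.09 and 4.08 in the authors' deposited table. The suberin list, genes of the endodermal wall polymer, had 12 of 12 tested members higher, at a median of 1.98, led by MYB41 (6.11) and KCS2 (4.64 in the authors' deposited table). The medians of the ABA-responsive, PP2C, transcription factor and suberin lists lay above all 10000 random lists of like expression, that of ABA synthesis and breakdown at percentile 99.9, and that of the receptors below all of them.

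The medians of the other 14 lists lay between -0.61 and 0.51. Among brassinosteroid biosynthesis genes 1 of 10 tested members rose and 3 fell (median -0.35, percentile 0.340), with CYP90D1 at -2.20 and DWF4 at 0.55 in the authors' deposited table. In brassinosteroid signalling 1 of 16 tested members rose and 4 fell (-0.10, percentile 5.98), and among brassinosteroid-induced genes 1 of 6 tested members rose and 2 fell (-0.61, percentile 0.470), a median that came inside the central 95% of random lists with genes under 1 FPKM left out. BKI1 and BEE1 fell, at -1.30 and -1.01 in the authors' deposited table. Of the wall-loosening expansins, 1 of 12 tested members rose and 4 fell (-0.20, percentile 5.57), with EXPA10 at -1.36 in the authors' deposited table, and of the xyloglucan endotransglucosylases 3 of 18 tested members rose and 4 fell (-0.08, percentile 4.65). Auxin early response genes had 7 rises and 3 falls among 17 (0.42, percentile 99.8), and IAA5 stood at 1.81 in the authors' deposited table. For auxin transport and root meristem patterning, 2 of 11 tested members rose and 3 fell (-0.22, percentile 2.85), with WOX5, a gene of the quiescent centre, at 1.29 in the authors' deposited table. Among mitotic cell cycle genes 2 of 17 tested members rose and 0 fell (0.18, percentile 95.7). Root hair genes had 3 falls in 16 (-0.15, percentile 2.66), among them RSL2 and RHD2 at -1.77 and -1.18 in the authors' deposited table. In epidermal patterning 1 of 8 tested members rose and 2 fell (-0.04, percentile 41.4), and in the Casparian strip list 2 of 7 tested members rose and 1 fell (0.08, percentile 63.2), with CASP5 at 2.04 in the authors' deposited table. Green tissue markers had 3 rises and 1 fall among 13 (0.24, percentile 93.3), and rapid stress and touch genes 4 rises and 1 fall among 7 (0.51, percentile 97.7). Of the 8 reference genes, 0 passed and 1 had an unadjusted p under 0.05 in the authors' test. Adjusted over the list alone, 13 of the 20 lists kept both counts, and the others moved by 1 gene: 8 rises for ABA synthesis and breakdown, 2 for brassinosteroid-induced genes, 4 for xyloglucan endotransglucosylases, 8 for auxin early response and 1 for mitotic cell cycle, and 4 falls for auxin transport and root meristem patterning and 2 for rapid stress and touch response.

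**Figure D2:**
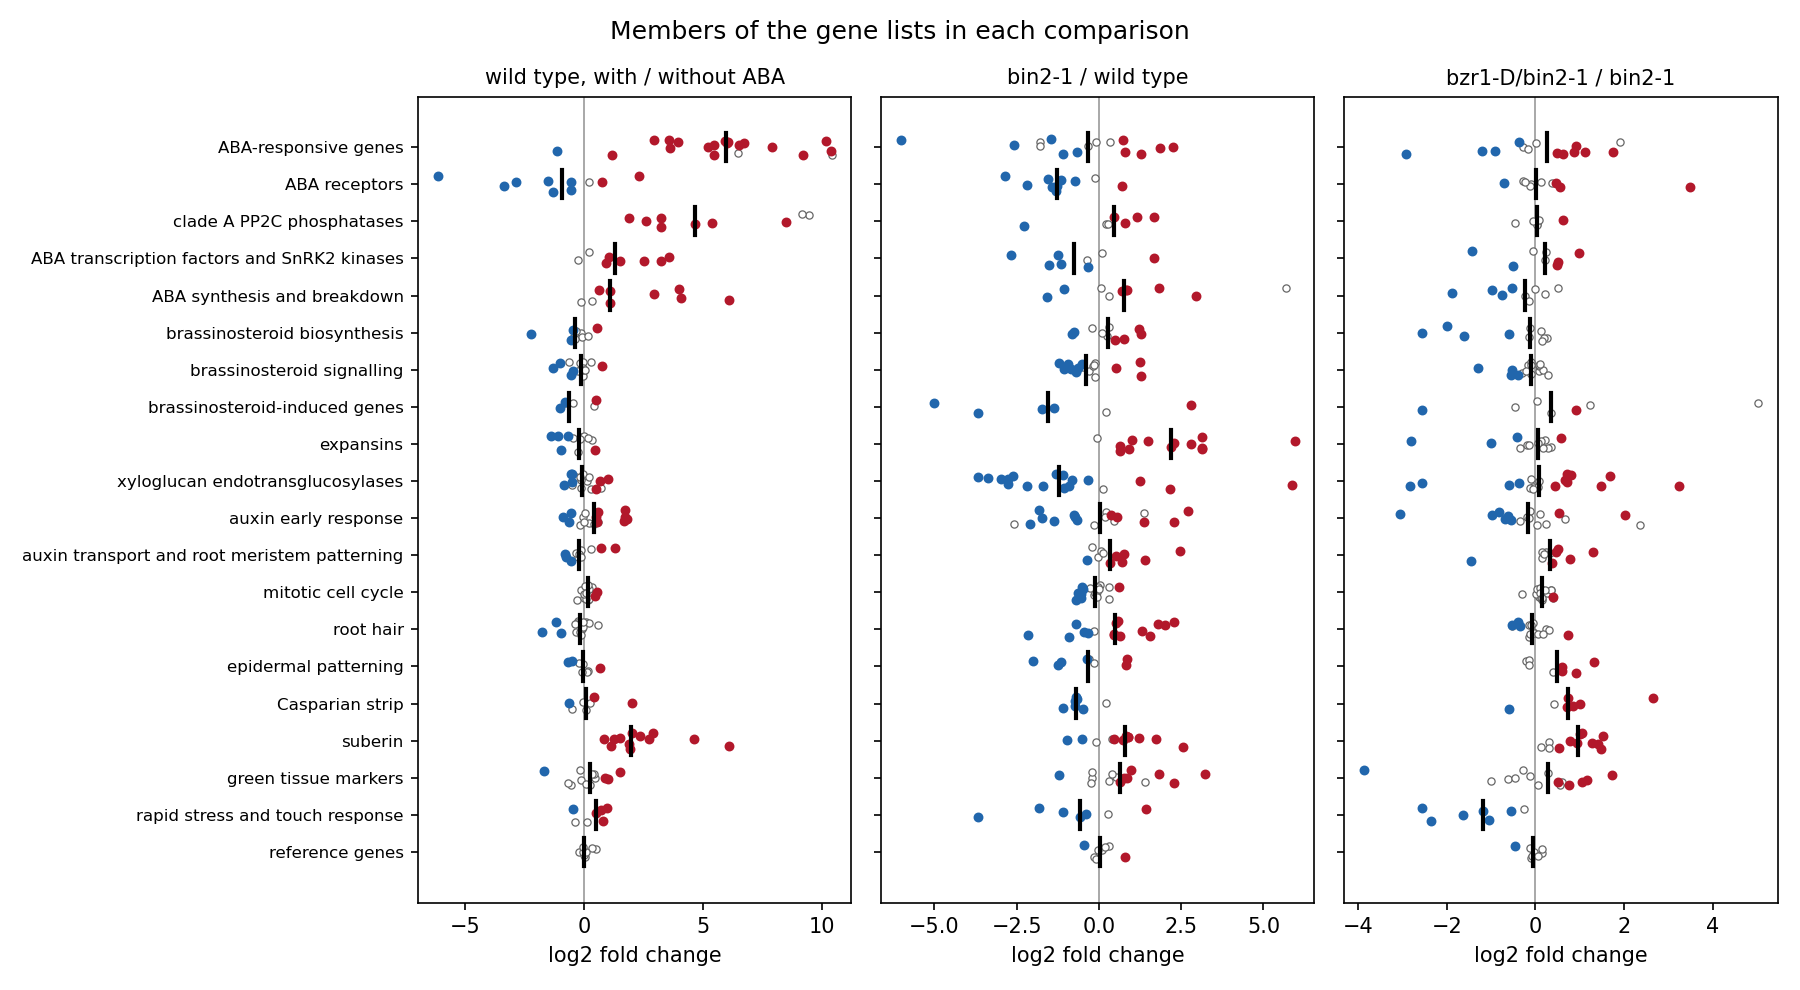
Log2 fold change (horizontal axis, with its own range in each panel) of the tested members of the 20 gene lists in the 3 comparisons, 1 point per gene. Red points rose and blue points fell at q under 0.05, open points did not pass, black bars mark the median, and 1 member listed at 0 in a group is not drawn. The ABA-responsive genes have a median of 5.98 with ABA and -0.34 in bin2-1, and the expansins -0.20 and 2.2.

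In bin2-1 roots 10410 of 20404 tested genes differed from untreated wild type, 5183 higher and 5227 lower, and 4266 of them at least 2-fold. The comparison asks what a hyperactive BIN2 changes in roots. Among genes past the threshold that reached 5 FPKM with a value above 0 in both groups, the largest falls were of NIP2;1, from 1750 to 13.5 FPKM (-7.02 on the log2 scale in the authors' deposited table), AT5G10040, from 614 to 5.29 FPKM (-6.86), AT4G28811 (-6.62), AT2G15960 (-6.52), AT3G19320 (-6.39) and SRO4 (-6.33). The largest rise was of AT1G60020, from 0.0288 to 37.6 FPKM (10.35 in the authors' deposited table, q = 0.0198), followed by AT5G45095 (7.88, q = 0.0346). The methyltransferase gene PXMT1, the nitrate transporter gene NRT2.6, CYP71A12, a cytochrome P450 of indole defence compounds, and AT5G41750 rose by log2 fold changes of 7.60, 7.18, 7.12 and 6.56 in the authors' deposited table. CYP71A12 has a near-identical neighbour, CYP71A13, with which it may share reads. Except where given, the q of these genes lay between 0.000188 and 0.00127 in the authors' deposited table.

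Cell wall genes moved in opposite directions. Of the expansins 12 of 13 tested members rose and 0 fell, with a median log2 fold change of 2.2 that lay above all random lists: EXPA17 went from 0.173 to 10.7 FPKM (5.95, q = 0.0404) and EXPA15 from 5.14 to 45.2 FPKM (3.14) in the authors' deposited table. Of the xyloglucan endotransglucosylases 14 fell and 3 rose among 18 (median -1.20, below all random lists), with TCH4, a touch-induced member, from 596 to 46.3 FPKM (-3.69) and XTH31 at 5.86 in the authors' deposited table. Brassinosteroid-induced genes had 4 falls and 1 rise among 6 (median -1.56, percentile 0.0300), with BEE1 from 15.2 to 0.469 FPKM (-5.02 in the authors' deposited table). The enzymes of brassinosteroid biosynthesis had 4 rises and 2 falls among 10 (median 0.28, percentile 90.5), and DWF4 and BR6OX2 rose by 1.22 and 1.28 in the authors' deposited table. For brassinosteroid signalling 3 of 16 tested members rose and 7 fell (-0.39, percentile 3.95).

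The ABA pathway list members went both ways in bin2-1. Among ABA-responsive genes 5 of 15 tested members rose and 5 fell (median -0.34, percentile 6.85), with ADH1 from 5208 to 80.4 FPKM (-6.02) and LEA7 at -2.58 in the authors' deposited table. ABA receptors had 8 falls and 1 rise among 10 (median -1.28, percentile 0.01), with PYL5 at -2.19 and PYL3 at -2.87 in the authors' deposited table. In the list of ABA transcription factors and SnRK2 kinases, ABI5 was the 1 member that rose and 5 of 8 fell (median -0.75, percentile 0.810), the kinase OST1 from 56.8 to 8.92 FPKM (-2.67 in the authors' deposited table). Of the PP2C phosphatases 4 of 7 tested members rose and 1 fell (0.47, percentile 89.7), with ABI1 at 1.66 in the authors' deposited table. For ABA synthesis and breakdown 5 of 10 tested members rose and 2 fell (0.76, percentile 97.8), with NCED3 at 1.82 in the authors' deposited table.

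Among the barrier genes of the endodermis, 6 of 7 Casparian strip genes fell (median -0.71, percentile 1.97), while 8 suberin genes rose and 2 fell among 12 (0.78, percentile 99.9), with ASFT at 2.57 in the authors' deposited table. Root hair genes had 10 rises and 5 falls among 16 (0.49, percentile 99.8), with EXPA7 at 2.28 and RSL2 at -2.15 in the authors' deposited table. In epidermal patterning 2 of 8 tested members rose and 4 fell (-0.33, percentile 11.1), with TRY 4.01-fold and GL2 2.36-fold lower in the authors' deposited table. Auxin transport and meristem patterning genes had 6 rises and 1 fall among 11 (0.33, percentile 93.3), with WOX5 from 1.94 to 10.7 FPKM (2.46 in the authors' deposited table). Auxin early response genes had 5 rises, among them IAA5 6.56-fold and GH3.3 4.91-fold in the authors' deposited table, and 7 falls among 18 (median 0.02, mean -0.13, percentile 58.8). Mitotic cell cycle genes had 1 rise and 6 falls among 17 (-0.13, percentile 28.9). Green tissue markers moved too: 7 of 15 tested members rose and 1 fell (0.65, percentile 98.0, and 94.4 with a pseudocount of 1 FPKM), with LHCB1.2, 1 of several near-identical genes, from 0.322 to 3.01 FPKM in the authors' deposited table. For rapid stress and touch genes 1 of 7 tested members rose and 5 fell (-0.57, percentile 5.16). Of the 8 reference genes, GAPC1 rose (0.78) and UBQ10 fell (-0.46) in the authors' deposited table. Adjusted over the list alone, 17 of the 20 lists kept both counts, and the falls came to 6 for ABA-responsive genes, 6 for ABA transcription factors and SnRK2 kinases and 9 for brassinosteroid signalling.

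Adding bzr1-D to bin2-1 changed 5056 of 20410 tested genes, 2435 higher and 2621 lower than in bin2-1, and 1795 of them at least 2-fold. The comparison asks which bin2-1 effects a stabilised BZR1 changes. The brassinosteroid biosynthesis genes DWF4, CYP90D1 and BR6OX2 fell by log2 fold changes of -1.99, -2.55 and -1.62 in the authors' deposited table, DWF4 from 15.4 to 3.86 FPKM. Among genes past the threshold that reached 5 FPKM with a value above 0 in both groups, the largest rises were of AT3G01345, from 0.118 to 141 FPKM (10.22 in the authors' deposited table, q = 0.00746), AT1G35320 (6.83), CIPK17 (6.31, q = 0.0336) and LSU4 (6.28, q = 0.0123). ACLA-2, a subunit of ATP-citrate lyase, rose from 1.01 to 71.9 FPKM (6.15), and LSU2, a sulfur-starvation gene, from 1.21 to 51.6 FPKM (5.42), in the authors' deposited table. The largest falls were of AT1G60020 (-8.39), AT5G44925 (-6.89), SADHU3-2, a retroelement (-6.32), and ARD3 (-5.88) in the authors' deposited table, followed by AT5G35935 (-4.62) and the blue copper protein gene BCB (-4.57). Where no q is given it was 0.000451, the smallest in the authors' deposited table.

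Barrier genes of the endodermis rose. In the suberin list 9 of 12 tested members rose (median 0.97, above all random lists), with CYP86A1 at 1.51 and FAR4 at 1.48 in the authors' deposited table. In the Casparian strip list 5 of 7 rose and 1 fell (0.74, percentile 99.99), with CASP5 at 2.65 in the authors' deposited table. Rapid stress and touch genes fell: 6 of 7 passed (-1.19, percentile 0.00500), with TCH4 at -2.56 and WRKY40 at -2.36 in the authors' deposited table. Xyloglucan endotransglucosylases had 8 rises and 4 falls among 18 (0.07, percentile 87.5), XTH21 at 3.23 and XTH23 at -2.84 in the authors' deposited table, and expansins 1 rise and 3 falls among 13 (median 0.05, mean -0.24, percentile 76.3), with EXPA10 at -2.81 in the authors' deposited table. Of the biosynthesis genes 4 of 10 fell, the fourth being CPD (-0.59 in the authors' deposited table), at a list median of -0.13 (percentile 15.8). In brassinosteroid signalling 4 of 16 fell (-0.10, percentile 19.4), among them BRL3 and BEH3 at -1.29 and -0.55 in the authors' deposited table. Among brassinosteroid-induced genes 1 of 7 tested members rose and 1 fell (0.34, percentile 93.6).

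In the ABA lists, ABA-responsive genes had 6 rises and 4 falls among 14 (median 0.25, percentile 99.1, and 67.8 with genes under 1 FPKM left out), with RD29A at 1.75 and RD22 at -2.93 in the authors' deposited table. For the receptors 3 of 10 tested members rose and 1 fell (0.02, percentile 64.6), for the PP2C phosphatases 2 of 7 tested members rose and 0 fell (0.04, percentile 61.6), and for the transcription factors and SnRK2 kinases 3 of 8 tested members rose and 2 fell (0.22, percentile 95.7). For ABA synthesis and breakdown 0 of 9 tested members rose and 4 fell (-0.24, percentile 7.42, and 1.67 with genes under 1 FPKM left out). Auxin early response genes had 2 rises and 6 falls among 18 (-0.16, percentile 8.44), with GH3.3 from 33.0 to 3.94 FPKM (-3.06 in the authors' deposited table). Of the auxin transport and meristem genes 5 of 11 tested members rose and 1 fell (0.32, percentile 99.5), with PLT1 2.46-fold higher and WOX5 2.75-fold lower in the authors' deposited table. In epidermal patterning 4 of 8 rose (0.50, percentile 99.6), with TRY at 1.33 and GL2 at 0.93 in the authors' deposited table. For root hair genes 1 of 16 tested members rose and 3 fell (-0.08, percentile 27.4), and for the mitotic cell cycle 1 of 17 tested members rose and 0 fell (0.15, percentile 93.8). Green tissue markers had 5 rises and 1 fall among 15 (0.29, percentile 97.2, and 99.9 with genes under 1 FPKM left out), and of 8 reference genes GAPC1 fell (-0.46 in the authors' deposited table). Adjusted over the list alone, 12 of the 20 lists kept both counts. The rises came to 7 for ABA-responsive genes, 4 for receptors, 3 for brassinosteroid-induced genes, 6 for the Casparian strip, 11 for suberin, 6 for green tissue markers and 0 for the mitotic cell cycle, and the falls to 4 for expansins and 2 for green tissue markers.

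Most genes that passed both in bin2-1 and on adding bzr1-D changed in opposite directions. Of 20097 genes tested in both comparisons, 3500 passed in both, 2622 (74.9%) in opposite directions and 878 in the same direction. Independent lists of these sizes would share 1277 genes in opposite directions and 1276 in the same direction. Among genes higher in bin2-1 and lower again in bzr1-D/bin2-1, AT1G60020 had log2 fold changes of 10.35 and -8.39, AT1G65200 of 5.08 and -5.20, AT1G48800 of 5.87 and -4.47, and AT4G12170 of 5.48 and -4.43 in the authors' deposited table of each comparison. Among those lower and then higher, AT1G58400 had -6.28 and 6.67, ACLA-2 -5.93 and 6.15, AT1G35320 -5.90 and 6.83, and CIPK17 -5.65 and 6.31 in the authors' deposited table of each. Of these examples, AT1G60020, AT1G65200, AT1G48800, AT1G58400, AT1G35320, ACLA-2 and CIPK17 lie on chromosome 1, as BZR1 does. Whether the mutant lines differ in sequence there was not tested, so these examples alone do not show a reversal by bzr1-D. PHI-1, AT2G14247, XTH23 and AT4G37710 fell in both, AT4G37710 with -3.01 and -3.71 in the authors' deposited table of each, and MLO14, AT1G63600, AT1G73490 and FRO5 rose in both. ABI5, DWF4 and BR6OX2 rose and then fell, and CASP5 and XTH21 fell and then rose. Among genes that passed in bin2-1, were tested on adding bzr1-D and had values above 0 in all groups, the 2036 at least 2-fold higher in bin2-1 had a median log2 fold change of 1.52 there and -0.30 on adding bzr1-D, and the 1967 lower ones -1.53 and 0.30. The bin2-1 libraries enter both ratios with opposite sign. In simulations with no effect, this alone made 66.6% of genes move in opposite directions. The observed share was 61.7% among 17453 genes of at least 1 FPKM in all groups. The simulated genes hold noise alone, unlike the data, so 66.6% is no baseline for the observed share. The observed share by itself shows no reversal. The covariance across genes was -0.16, and -0.02 in the simulations. The simulations leave out any growth or harvest state shared by the bin2-1 libraries, which would also move genes in opposite directions.

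**Figure D3:**
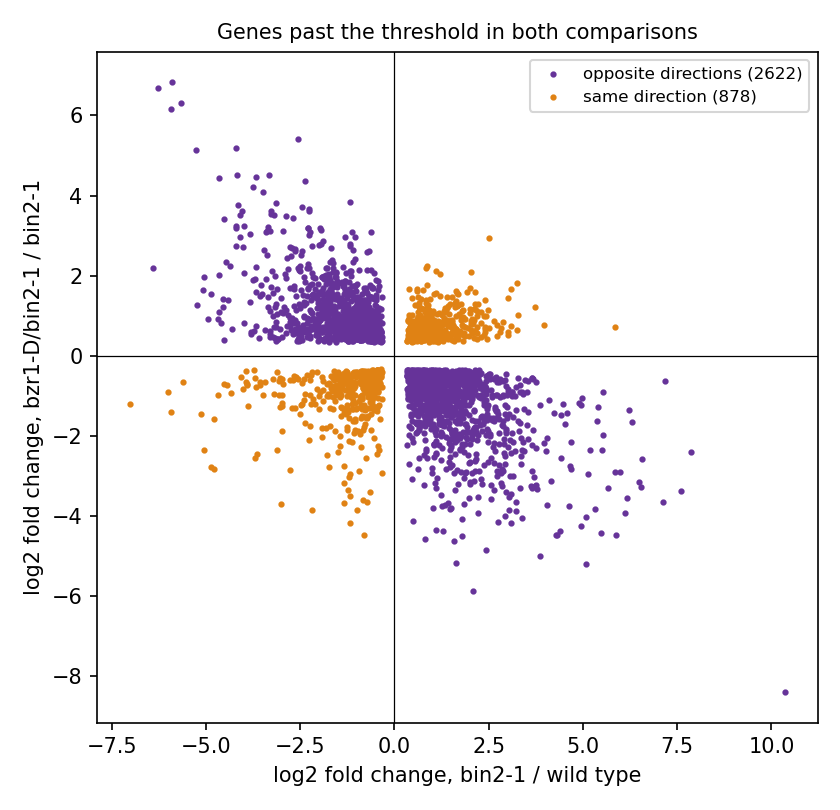
Log2 fold change in bin2-1 against wild type (horizontal axis) and in bzr1-D/bin2-1 against bin2-1 (vertical axis) for genes at q under 0.05 in both comparisons, 1 point per gene; 60 genes listed at 0 in a group are not drawn. Purple points, in opposite directions, stand for 2622 genes and orange points for 878 genes.

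Many genes passed in the same direction with ABA and in bin2-1. Of 19815 genes tested in both comparisons, 3272 passed in both, 2189 (66.9%) in the same direction and 1083 in opposite directions, where independent lists would share 1230 and 1248. Higher in both were AT2G34610, PMAT1, AER and LSU1: PMAT1 had log2 fold changes of 5.83 with ABA and 4.62 in bin2-1 in the authors' deposited table of each. Lower in both were AT1G44050, AT2G36690, NIP2;1 and AT4G28811, and AT1G44050 had -5.57 and -4.65 in the authors' deposited table of each. Higher with ABA and lower in bin2-1 were AT3G07250, AT3G53040, AT4G25580 and TLP-3, the last with 3.51 and -3.16 in the authors' deposited table of each. Lower with ABA and higher in bin2-1 were AT3G06437, AT4G08780, AT5G43520 and CDEF1, AT4G08780 with -2.49 and 2.12 in the authors' deposited table of each. Genes higher in both (1101) and lower in both (1088) exceeded the numbers of independent lists, 725 and 504. Both ratios share the untreated wild type as denominator: in simulations with no effect this alone put 66.7% of genes in the same direction. The observed share was 57.8% among 17331 genes of at least 1 FPKM in all groups. The simulated genes hold noise alone, unlike the data, so 66.7% is no baseline for the observed share. The observed share by itself shows no common direction. The covariance across genes was 0.15, and 0.02 in the simulations. The simulations leave out any growth or harvest state shared by the untreated wild-type libraries, which would also move genes the same way.

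ABA and bzr1-D shared more genes past the threshold than independent lists would, in each of the 4 direction patterns. Of 19584 genes tested in both comparisons, which share no libraries, 2036 passed in both, 1163 (57.1%) in opposite directions and 873 in the same direction, where independent lists would share 593 and 586. The genes higher with ABA and lower on adding bzr1-D numbered 762 against 370 in independent lists, those lower and then higher 401 against 223, those higher in both 560 against 351 and those lower in both 313 against 235. Independent lists take no account of expression, so genes that pass more readily in any comparison could give an excess in all 4 patterns. Across 17193 genes of at least 1 FPKM in all groups, 52.4% moved in opposite directions, against 50% in simulations with no effect, and the covariance across genes was -0.0122. Genes higher with ABA and lower on adding bzr1-D included ABI5, PMAT1, AT1G05562, 5PTASE11 and AOX1D, the last with log2 fold changes of 3.39 and -3.54 in the authors' deposited table of each. Lower with ABA and higher on adding bzr1-D were AT2G31730, MYB27, CYP702A2 and HOL2, and HOL2 had -3.55 and 3.25 in the authors' deposited table of each. Higher in both were AT3G21670, AT4G33550, CHX17 and LOG5, a cytokinin-activating enzyme gene, with 5.16 and 2.58 in the authors' deposited table of each. Lower in both were AT1G34047, PP2-A3, CYP90D1 and AT4G08780, and CYP90D1 had -2.20 and -2.55 in the authors' deposited table of each.

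Strong changes in bin2-1 were not spread evenly along the chromosomes. In gene order, with windows of 100 tested genes, 1375 of 20244 genes on chromosomes 1 to 5 passed and changed at least 4-fold in bin2-1, and 4 of 199 windows held more than 17, the 95th percentile of the highest window over 1000 shuffles. From AT3G27080 to AT3G46290 on chromosome 3, a stretch of 4 windows with 3 above that bound, 79 of 400 tested genes (19.8%) changed at least 4-fold, 51 of them higher, against 6.53% of genes elsewhere. From AT5G44090 to AT5G45275 on chromosome 5, 24 of 100 did, 17 of them higher. Of these changes, 23 of the 79 on chromosome 3 and 10 of the 24 on chromosome 5 were genes listed at 0 in a group. The named genes XTH31, NRT2.6, BR6OX2, FAR4, SADHU3-2, AT5G44925 and AT5G45095 lie within these stretches. Some chromosome 1 windows came close to the bound of 17 without passing it. Those from AT1G50930 to AT1G52343, AT1G52347 to AT1G53580 and AT1G53590 to AT1G54740 held 15, 15 and 14 such genes. Those from AT1G60680 to AT1G61930, AT1G64480 to AT1G65820 and AT1G65840 to AT1G67280 held 15, 14 and 14. Windows between held fewer, such as 6 from AT1G54760 to AT1G55910. With ABA 13 of 379 tested genes of the chromosome 3 stretch changed as much, and on adding bzr1-D 15 of 392. With ABA 1 window, on chromosome 1 from AT1G68490 to AT1G69588, held 13 genes, above the shuffled bound of 12.

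**Figure D4:**
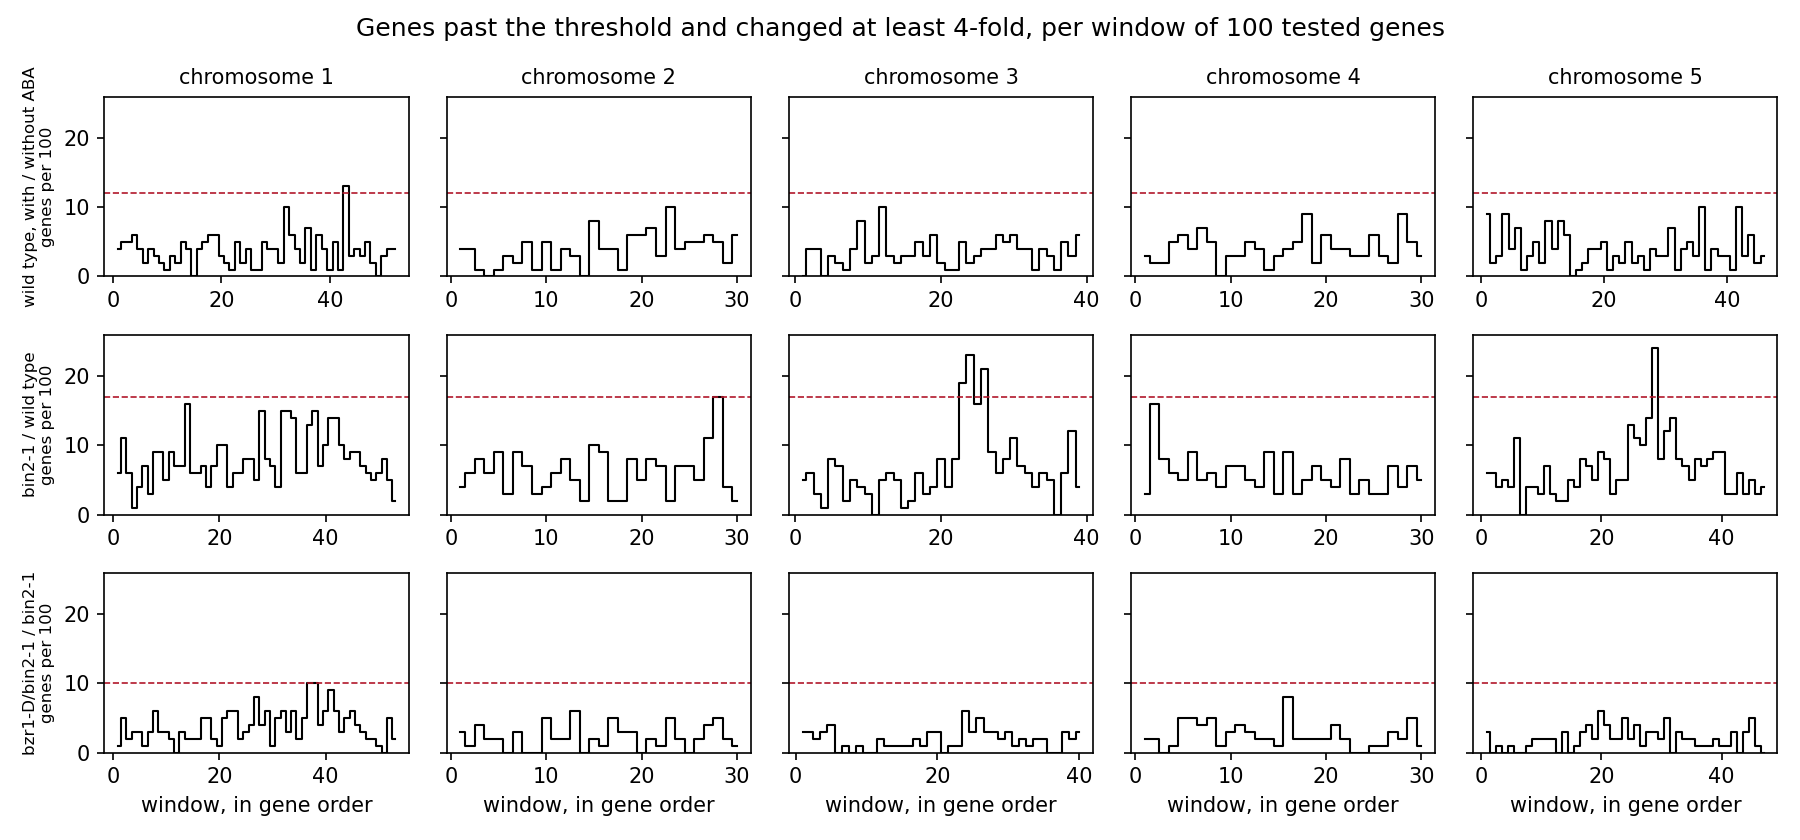
Number of genes at q under 0.05 and changed at least 4-fold (vertical axis) in each window of 100 tested genes along chromosomes 1 to 5 (horizontal axis, windows in gene order) for the 3 comparisons. The dashed line is the 95th percentile of the highest window over 1000 shuffles; in bin2-1 3 of the 4 windows of the chromosome 3 stretch and 1 window of chromosome 5, with 24 genes, lie above it.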

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

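3 genes that entered no test in the bin2-1 table, because the authors gave them a p of 1, were listed at 0 in untreated wild type and above 100 FPKM in bin2-1. AT3G41768, a ribosomal RNA gene, had 1068 FPKM in bin2-1 and was listed at 0 in ABA-treated wild type. In the comparison of the mutants it had 1114 FPKM in bin2-1 and 1131 FPKM in bzr1-D/bin2-1. ATCG00220, a chloroplast gene, had 283 FPKM in bin2-1 in the comparison with wild type, and 296 FPKM in bin2-1 beside 279 FPKM in bzr1-D/bin2-1. In the separately scaled ABA comparison it had 2163 FPKM in ABA-treated wild type. AT3G12835, a protein-coding gene of 105 annotated bases, had 223 FPKM in bin2-1 and was listed at 0 in ABA-treated wild type and in bzr1-D/bin2-1. The difference from wild type was not tested for these genes, and a value listed at 0 can be a failed estimate.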

How the results depend on the processing

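Leaving out the chromosome windows dense in strong changes was chosen after seeing the data. The counts of genes past the threshold, in total and higher, stayed within 1.5 times under a q of 0.01, the 1 FPKM filter, the recomputed adjustment and centring, and so did the overlaps under the filter and centring. Without the dense windows the 4 counts with ABA and in bin2-1 stayed within that range, and the bzr1-D comparison had no such window. A minimum of 2-fold moved each count by its construction. With ABA it left 2236 genes, 1575 of them higher, in bin2-1 4266 and 2147, and for bzr1-D 1795 and 836. It left 808 genes in opposite and 143 in the same direction for bin2-1 and bzr1-D, 224 and 724 for ABA and bin2-1, and 250 and 208 for ABA and bzr1-D. At a q under 0.01 in both comparisons, a stricter limit by construction, 1735 opposite and 514 same-direction genes were left for bin2-1 and bzr1-D, 716 opposite ones for ABA and bin2-1, and 728 opposite and 540 same-direction ones for ABA and bzr1-D. A pseudocount of 1 FPKM, which shrinks the change of low genes, left 1165 bzr1-D genes changed at least 2-fold, against 1795, while a pseudocount of 0.1 kept the 3 such counts within 1.5 times. Centring kept all 60 list medians on their side of the central 95% of random lists, and the 1 FPKM filter and the pseudocount of 1 kept 56 each. With the filter the median was -0.18 (percentile 11.2) for brassinosteroid-induced genes with ABA and 0.0160 (percentile 67.8) for ABA-responsive genes with bzr1-D, both no longer outside that range, and -0.38 (percentile 1.67) for ABA synthesis and breakdown and 0.51 (percentile 99.9) for green tissue markers with bzr1-D, now outside it. With the pseudocount it was -0.24 (percentile 3.64) for brassinosteroid-induced genes with ABA and 0.36 (percentile 94.4) for green tissue markers in bin2-1, no longer outside, and -0.14 (percentile 2.00) for root hair genes with ABA and 0.26 (percentile 98.9) for green tissue markers with bzr1-D, now outside. The cause was not tested for these lists. The 231 finite named values kept their direction under centring and the pseudocount of 1. No paired analysis was possible because the tables used here hold 1 value per group. Leaving out each replicate, a count model and a choice by test status were not run, the first 2 for the same reason and the last because no status was used here. The depth is unknown, and in simulated data with errors taken from the deposited p and fold changes 83% to 84% of 2-fold changes were recovered. The simulated p were computed from those same errors, so this share does not measure the power of the authors' test.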

Other observations

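The gene groups in this part, the tests on the hypoxia genes and on centromere-near position, and the error ratio among genes that moved little, were chosen after the result was seen, and the other tests before. Low-oxygen (hypoxia) genes fell together: 19 of 19 in bin2-1, at a median log2 fold change of -3.90, and 17 with ABA, at -1.28. ADH1 and PDC1, the fermentation enzymes, had -6.02 and -5.14 in bin2-1 in the authors' deposited table, ADH1 from 5208 to 80.4 FPKM. These 19 genes made up 1.78% of all FPKM in untreated wild type and 0.0809% in bin2-1. On adding bzr1-D, 12 fell further and 3 rose. Small heat shock protein and heat response genes fell in bin2-1 too, 11 of 13 (median -4.07), with HSP17.6II at -6.03 in the authors' deposited table. Of the same list, 6 of 13 rose and 0 fell with ABA and 0 of 11 rose and 4 fell on adding bzr1-D.

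Sulfur-deficiency genes had 9 rises and 3 falls among 15 in bin2-1 (median 1.89): GGCT2;1 and LSU1 had 5.49 and 3.98, and the sulfate transporters SULTR1;1 and SULTR1;2 -2.78 and -2.29, in the authors' deposited table. LSU2 stood apart from LSU1, at -2.54 in bin2-1 and 5.42 on adding bzr1-D in the authors' deposited table of each. LSU4 (AT5G24655), whose identifier lies next to that of LSU2 (AT5G24660), moved the same way. It had -1.92 in bin2-1, without passing (q = 0.0696), and 6.28 on adding bzr1-D in the authors' deposited table of each. For this list 3 of 14 rose and 1 fell with ABA and 2 of 15 rose and 6 fell on adding bzr1-D. Of 5 genes of camalexin, an indole defence compound, 4 of 5 rose and 1 fell in bin2-1, 0 of 5 rose and 3 fell on adding bzr1-D and 1 of 3 rose and 1 fell with ABA. Of the glutathione transferases of the GSTU family, 16 of 27 rose and 3 fell in bin2-1 (median 1.04), 2 of 27 rose and 17 fell on adding bzr1-D (-0.90), and 16 of 26 rose and 2 fell with ABA (0.72). On adding bzr1-D, 0 of 10 rose and 8 fell of the JAZ repressors of jasmonate signalling (-1.36), and 8 of 57 rose and 27 fell of the WRKY factors (-0.48), while in bin2-1 1 of 10 rose and 4 fell of the JAZ genes and 18 of 58 rose and 19 fell of the WRKY genes. With ABA 6 of 10 rose and 1 fell of the JAZ genes, and 20 of 57 rose and 9 fell of the WRKY genes. Secondary wall and xylem genes rose on adding bzr1-D, 10 of 14 (0.79), with the cellulose synthase gene CESA8 at 1.19 in the authors' deposited table, while in bin2-1 2 of 14 rose and 4 fell and with ABA 3 of 14 rose and 0 fell. Of the UGT glycosyltransferases 20 of 45 rose and 3 fell with ABA, 25 of 46 rose and 8 fell in bin2-1 and 12 of 46 rose and 16 fell on adding bzr1-D.

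The fall of the hypoxia genes in bin2-1 was not a matter of scaling, since the median of all genes moved by -0.0213 on the log2 scale. The median difference of bin2-1 from ABA-treated wild type was -2.79 (quartiles -3.73 and -2.05), lower for 19 of 19. HRE1 barely differed, at -3.91 with ABA and -3.95 in bin2-1 in the authors' deposited table of each. This argues against unusual untreated wild-type libraries alone only if ABA itself did not raise these genes, which was not tested. Lowered BZR1 activity would predict a rise on adding bzr1-D for genes that bzr1-D restores. Of the brassinosteroid-induced genes, however, 1 of 7 tested members rose and 1 fell there. The median of the hypoxia genes there was -0.65 (quartiles -1.05 and -0.18), with 16 genes lower. The missing rise therefore speaks only to BZR1 effects that bzr1-D restores. In bzr1-D/bin2-1 the hypoxia genes stood at -4.60 against wild type. A difference in growth or harvest between wild-type and mutant roots, such as oxygen supply at harvest, would give this. An effect of the bin2-1 kinase that bzr1-D does not undo would too. These cannot be told apart, because genotype and any such difference coincide.

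Dense 4-fold changes on chromosomes 3 and 5 in bin2-1 were not explained by tandem gene families as a whole: with 1 gene kept per annotated product and window, 3 windows still exceeded the shuffled bound of 16. Nearness to the centromere is argued against for chromosome 5, whose stretch lies away from its least gene-dense window, which held 3 such genes. For chromosome 3 it cannot be told apart from the other explanations, because the stretch includes the least gene-dense window, with 23 such genes, while those of the other chromosomes held a median of 5.50 and that of chromosome 1 held 15. A candidate explanation is also a stretch of another haplotype carried by both mutant lines, whose changes bzr1-D would reverse less often than changes elsewhere: among those with values above 0 in wild type and bin2-1 and tested on adding bzr1-D, 43.1% of 58 inside the dense windows then passed in the opposite direction, and elsewhere 47.3% of 1092 (Fisher's exact test, two-sided p = 0.590), so haplotype and regulation cannot be told apart here, for want of sequence. No biological explanation specific to these stretches was tested.

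Of the tested genes 51.0% passed in bin2-1, against 24.6% with ABA. A smaller error within the authors' test is argued against: the standard error implied by the deposited p and fold changes was 0.949 times that of the ABA comparison, between the medians of 9112 and 11145 genes of at least 5 FPKM, which leave out genes at the smallest p. Among 6395 such genes that moved by under 0.5 on the log2 scale in both comparisons, 0 of them at the smallest p in either, the median ratio was 0.943 (quartiles 0.929 and 0.958). The authors' test is not named, so these ratios do not measure the spread between libraries. A scaling factor would shift the fold changes without spreading them, but their interquartile range was 1.86 times that with ABA. The spread of bzr1-D/bin2-1 against wild type was 1.87 times its spread against bin2-1, as shared plates, harvest or sequencing pool of the mutant libraries would give, and as the shared bin2-1 mutation would, so these cannot be told apart, because no label gives a plate, day or pool and genotype would coincide with them.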
